A study of Mus musculus with 300 samples.

How the data were processed

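Early thymic progenitors (ETPs) of the embryonic day 15.5 thymus of mice with reporters at the Id2, Gata3, Rora and Bcl11b loci were profiled by single-cell RNA sequencing. Per the labels' protocols, single cells were sorted into plates and lysed in a Triton buffer, reverse transcription was primed with oligo-dT, and cDNA was amplified by PCR and made into indexed Nextera XT libraries that were sequenced in 2 pools. The labels give 300 cells of 1 group from 4 mouse ids: 73 of mouse 1A, 80 of 1B, 76 of 2A and 71 of 2B. They name no treatment and no second group, so no groups were compared and every test asks which genes vary together among the cells of each mouse. Whether a mouse id stands for 1 embryo or for several, and how the cells were gated, is not given in the sources used here.

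The authors' deposited matrix holds 13737 features for 261 of these cells (67, 69, 64 and 61 of mice 1A, 1B, 2A and 2B), and the other 39 cells were not analysed here. The deposited values are normalized expression on a log2 scale after a batch correction by the authors, and run from -4.13 to 15.99. Salmon and the build GRCm38 are named per the submitters' processing notes, without versions; the depth normalization, the correction tool and the filters are not given in the sources used here. The planned analysis expected TPM or counts, so the rank-based test written for both was kept and the deposited log2 values were used as they are. In the matrix, 4 sets of cells were recognised by exact shared values: any 2 cells of a set shared at least 14.2% of their values, and cells of different sets shared 0%. Within a set each gene has a repeated lowest value, which was taken as its level at no reads; a gene was called detected in a cell when its value differed from that level by more than 1e-06. A set lacks such a level for a gene that had reads in nearly every cell, and 12054 genes had it in all 4 sets. The level differs between sets. Cells of a labelled mouse without reads of a gene can thus differ in rank when they belong to different sets. "A level of at least 10" means a linear value of at least 10 above the level at no reads. Read depth per cell is not given in the matrix, so depth is given as the number of detected genes: a median of 7782 per cell (5073 to 10337), by mouse 7518 (1A), 7544 (1B), 7787 (2A) and 8243 (2B), with a median mitochondrial share of 3.24% (1.05 to 7.09%). All 261 cells passed the filters of at least 1000 detected genes and at most 20% mitochondrial signal. With 61 to 69 cells per mouse, shares carry exact 95% Clopper-Pearson intervals that cover counting error only, and a share of 0 is bounded with a floor of 3 cells.

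Gene IDs were matched without their version to GENCODE vM21 symbols (13578 IDs matched, 154 without a symbol), and positions are those of GRCm38. Transgene transcripts in the matrix were assigned to loci from knowledge of the strain: tagBFP to Id2, hCD2 to Gata3, mTeal to Rora and TdTomato to Bcl11b. A further reporter locus is not reported here.

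For Rora, Bcl11b, Gata3 and Id2, each detected in at least 10% of cells, every other gene detected in at least 10% of cells was tested. Inside each mouse a partial Spearman correlation was computed between gene and reporter gene, given the rank of the number of detected genes and the plate. The 4 Fisher z values per gene, 1 per mouse, were tested against 0 with limma 3.58.1 in R 4.3.3 (two-sided, intercept only, no trend) and adjusted with Benjamini-Hochberg over all genes tested at 0.05. The mean rho is the back-transformed mean z, given with the SD of the 4 rhos, and the slope is the log2 change of the gene per 1 SD of the reporter gene. Rora and Bcl11b were compared by testing the difference of their z values in the same way. The p-values rest on the 4 labelled mice, and cells were not used as replicates. Mice 2A and 2B draw mostly on the same sets of cells with shared values. Set 2 holds 35 cells of 2A and 36 of 2B, and set 4 holds 26 and 25. If the sets follow the animal, these mice are not independent units and p is too small. The moderated test of limma draws each gene's variance toward that of all genes tested. A gene can thus be called although its own rho varies widely among mice, and p does not measure that spread alone.

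The gene lists were fixed from knowledge of the tissue: progenitor, T specification, Notch targets, innate lymphoid cells (ILC), natural killer (NK), lymphoid tissue inducer and ILC3 (LTi/ILC3), gamma-delta T, myeloid, macrophage, dendritic, B cell, erythroid and megakaryocyte, mast and basophil, thymic stroma, S phase, G2M phase, immediate early and Y-linked genes. Some lists share genes, so their tests are not independent: Cxcr5, Lta, Ltb and Il1r1 are in both ILC and LTi/ILC3, and Tcf7 and Ets1 in both T specification and ILC. Each of the 18 lists was tested with limma's camera (preset inter-gene correlation 0.01, lists with at least 4 tested genes, the reporter gene itself taken out), adjusted over 72 tests. Camera with an estimated correlation and fry were run beside it. Scores per cell for 6 lists (mean standardised value of genes detected in at least 5% of cells, genes of 2 lists left out) were related inside each mouse by partial Spearman correlation, with an exact two-sided sign-flip test over mice. Clusters came from Ward clustering of 20 principal components of the 1000 most variable genes, centred per plate, without mitochondrial and sex-linked genes, into 5 clusters; 4 and 8 clusters, no centring and Leiden clustering of a 15-neighbour graph were tried beside it. Clusters describe the cells, and their leading genes were not tested. A cluster was called by a cell type when its 10 leading genes held several markers of that type's list. For the 8-cluster version a rule was set after its genes were seen: at least 2 markers of types outside the T and ILC lineages marked cells of another type, and at least 3 NK or ILC markers marked NK/ILC-like cells. No doublet caller was run.

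Genes named in the text follow a fixed rule: among genes past the threshold with the same sign in 4 mice, up to 10 highest and 10 lowest by mean rho for Rora and Bcl11b, and up to 5 each for Gata3, Id2 and the difference of Rora and Bcl11b, leaving out predicted (Gm, Rik), mitochondrial and ribosomal genes; the reporter genes; for each list with a stated count, its members past the threshold or, if none, the 2 with the largest absolute rho; and the 10 leading genes of each cluster. Other genes were chosen after their values were seen, and are given as members of a list that pass when adjusted over the list alone, as genes left in an alternative, or as detection values. The tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Chosen after the data were seen were the use of the correction sets as units or covariate, aligned zero levels, plate row as covariate, mice with at least 5 detected cells, plate JW8 left out, levels under 10 set to 0, NK/ILC-like cells left out, the first 8 wells of each correction set left out (8 being the longest run of NK/ILC-like cells) and the reporter transcripts. The median-ratio alternative was recomputed from linear values with zeros restored, because its earlier form broke ties at zero.

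The alternatives chosen beforehand covered covariates, Pearson correlation with pseudocounts 1 and 10, gene filters (25% of cells, or 3 cells per mouse), at least 2000 detected genes, 8 wells with doubtful mouse labels left out or swapped, plate as unit, the first pool alone, other cell types left out, rescaling by median ratios, and leaving out each mouse. The labels of those wells are doubtful because the mouse ids follow the text-sorted order of the titles rather than well order. The procedure was tested on simulated data, 50 genes per effect with Id2 reassigned among the cells: 40% of genes at a rho of 0.2, 92% at 0.3 and 100% at 0.4 and 0.5 were called, with 9 false calls among 12432 genes run. The simulation used Id2, which most cells carry, and the same rho in each mouse apart from sampling noise. Its rates do not carry over to Rora and Bcl11b or to rhos that differ among mice. The levels of each reporter gene were also reassigned 99 times among the cells of a plate and mouse. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.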

Results

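Transcripts of progenitor and early T-lineage genes were detected side by side in most cells analysed. These shares are over all cells, and dendritic-, mast-, macrophage- and NK/ILC-like cells, described below, are among them. Cd34 was detected in 94.6 ± 3.12% of cells (mean ± SD of 4 mice), the stem cell factor receptor Kit in 91 ± 5.70%, the T-cell kinase Lck in 98.1 ± 2.29%, and Tcf7, which encodes TCF-1, in 81.2 ± 11.5%. Il2ra, which marks later T-lineage commitment, was detected in 54.7 ± 16.2% and the T-cell receptor component Cd3e in 6.66 ± 3.80%. Across the fixed lists, the median gene was detected in 79.5% of cells for progenitor, 57% for T specification, 35.5% for ILC and 22% for NK genes. Genes of cell types outside the T and ILC lineages spanned the same range, with 12% for B cell, 19.3% for thymic stroma, 20.1% for macrophage, 27.1% for mast and basophil, 38.6% for erythroid and megakaryocyte, 39.4% for myeloid and 56.2% for dendritic genes, so the T specification, ILC and NK medians do not stand clearly above this background.

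Gata3 and Id2 were widespread among the cells analysed, whereas Rora and Bcl11b were found in a minority. Gata3, a regulator of T-cell and ILC development, was detected in 83 ± 6.03% of cells and Id2, an inhibitor of E proteins, in 86 ± 6.24%. Rora, a nuclear receptor required for ILC2 development, was detected in 28 ± 20.1%, with 22.4, 4.35, 32.8 and 52.5% in mice 1A, 1B, 2A and 2B. Bcl11b, the T-lineage commitment factor, was detected in 14.2 ± 11.4% (5.97, 2.90, 23.4 and 24.6%). At a level of at least 10 the shares were 71.5 ± 7.37% for Gata3, 66.4 ± 7.37% for Id2, 7.77 ± 3.12% for Rora and 8.31 ± 6.68% for Bcl11b. The Rora and Bcl11b shares followed the sequencing pool: Rora was detected in 12.7% of cells of the first pool and 52.1% of the second, Bcl11b in 5.45% and 28.1%. Within mouse 2A, whose cells lie in both pools, Rora was detected in 10.3% and 51.4% and Bcl11b in 10.3% and 34.3%. Differences between mice of different pools thus cannot be separated from the pool. The 2A cells of the first and second pool also belong to different correction sets, so whether they come from the same animal is not settled. Mice 1A and 1B, both in the first pool, lie mostly on different plates (52 of 67 cells on AF2, and all 69 on AF1).

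**Figure D1:**
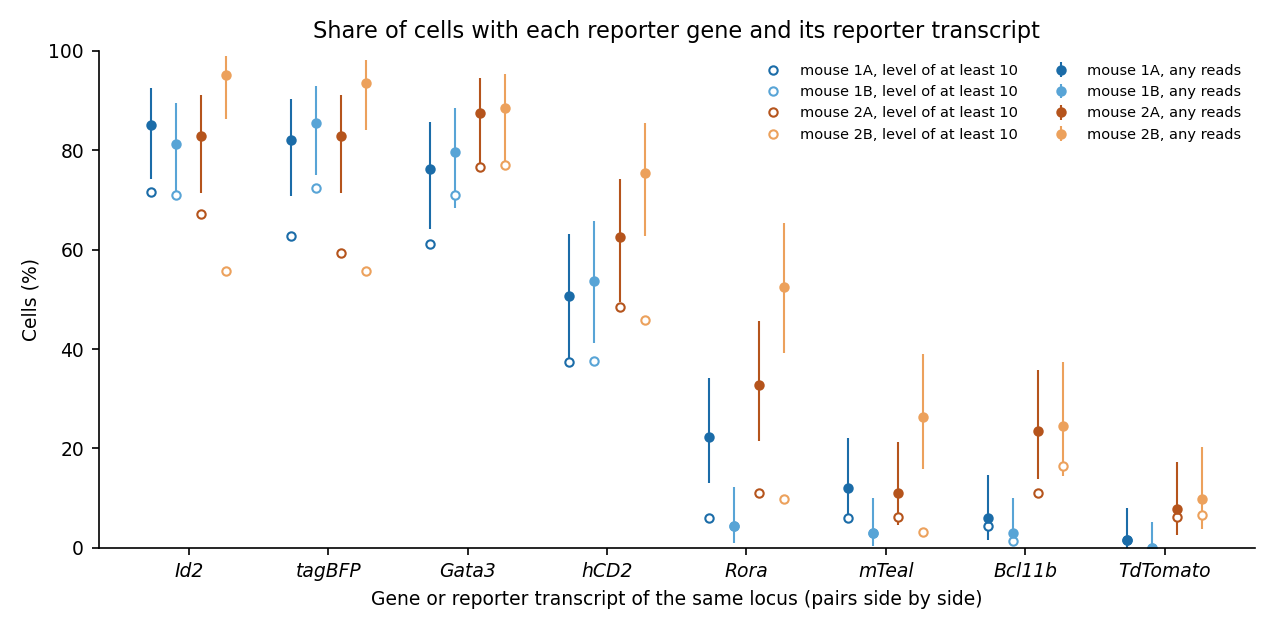
Percent of cells per labelled mouse with each reporter gene and reporter transcript, at any reads (filled points, with exact 95% intervals for counting error) and at a level of at least 10 (open points). Id2 and Gata3 lie between 76.1 and 95.1% in every mouse, whereas Rora runs from 4.35 to 52.5% at any reads and from 4.35 to 10.9% at a level of at least 10.

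**Figure D2:**
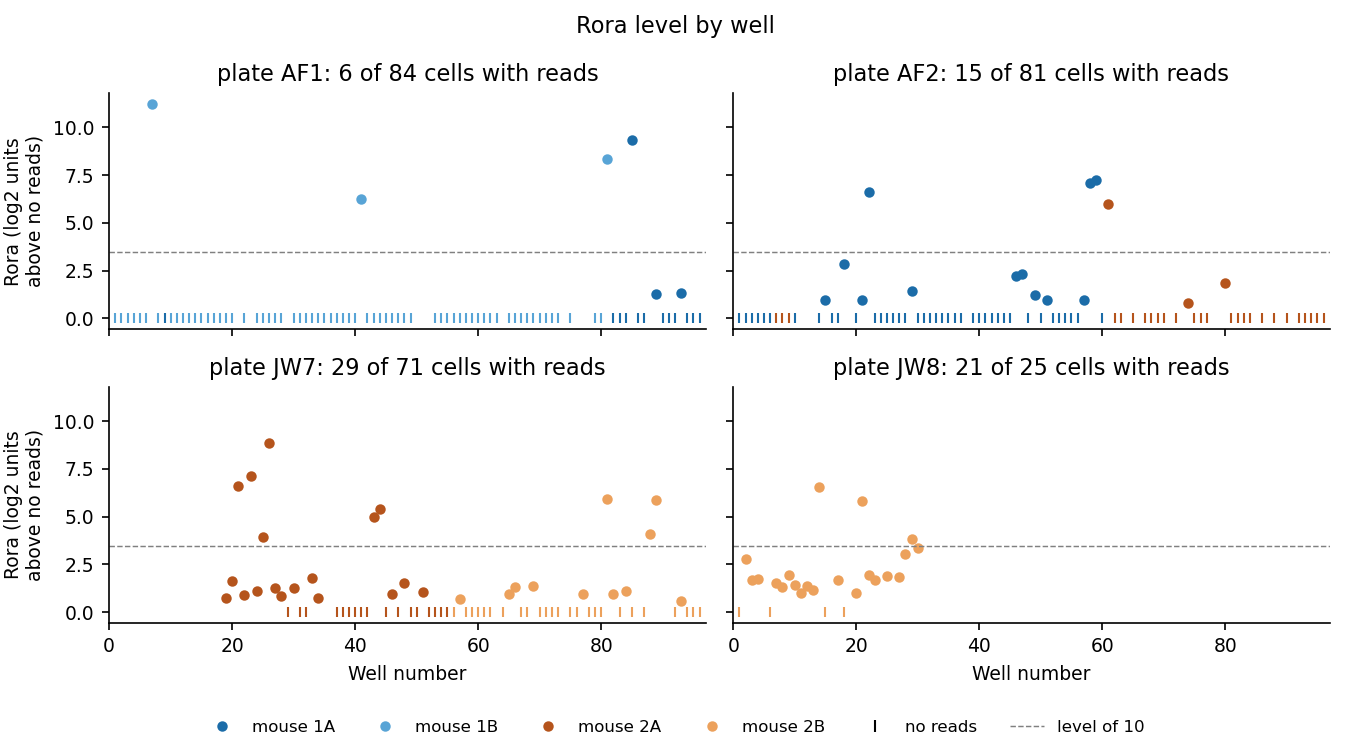
Rora level (log2 above the level at no reads) by well number on the 4 plates, coloured by labelled mouse, with a dashed line at a level of 10. Rora was detected in 7.14% of cells on plate AF1, 18.5% on AF2, 40.8% on JW7 and 84% on JW8, mostly below the line, above which lie 4, 4, 9 and 3 cells.

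Gata3 and Id2 transcripts occurred together in most cells analysed, and those of Rora and Bcl11b in few. Gata3 and Id2 were found together in 71.6% of cells, against 71.5% given by the product of their shares. Rora was found with Id2 in 26.4% against 24.9%, an excess of 1.53 ± 0.80 percentage points present in 4 of 4 mice. Rora and Bcl11b shared 19 cells, 7.60% against 5.51% (excess 2.09 ± 2.20, 3 of 4 mice). These shares are described without a test and without adjustment for depth.

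Reporter transcripts followed the gene of their locus for Id2, Gata3, Rora and Bcl11b. The mean rho inside mice was 0.777 ± 0.068 for tagBFP with Id2, 0.648 ± 0.096 for hCD2 with Gata3, 0.669 ± 0.306 for mTeal with Rora and 0.552 ± 0.088 for TdTomato with Bcl11b (3 mice, since TdTomato was detected in 0 of 69 cells of mouse 1B, a share under 4.35% with the floor of 3 cells). For mTeal the value was 0.926 in mouse 1B, where Rora had 3 detected cells, and 0.182 in mouse 2B. TdTomato was detected in 12 of the 36 Bcl11b cells and in no cell without Bcl11b. The reporter transcripts were added after the data were seen.

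The cells formed a progenitor-like cluster, a cycling cluster, a mixed lymphoid and innate cluster, and smaller clusters. Cluster 1 (97 cells, 37.2 ± 3.44% per mouse) was progenitor-like, led by Pdgfrb, Cd34, Kcnn4, Adgrg1, Mycn, Dnmt3b, Myb, Kit, Nfe2 and Anks1, which were 2.45 to 3.53 log2 higher than in the other cells. Cluster 2 (87 cells, 33.3 ± 6.89%) was led by the cell-cycle genes Aurkb, Pbk, Ccnf, Cdca5, Espl1, Aurka, Cdk1, Mybl2, Ccnb1 and Top2a (3.88 to 4.72 log2). Cluster 3 (47 cells, 17.9 ± 3.63%) had Lgals3, Fgl2, Adgre5, Sema4a, Pglyrp1, Skap1, Il2rb, Klrk1, Itm2c and tagBFP (4.40 to 6.24 log2). Cluster 4 (19 cells, 7.22 ± 5.14%) was dendritic-like, led by Siglech, Pld4, Irf8, Ly6d, Ctsh, Ccr9, Spib, Mpeg1, Ly86 and Ighm (7.77 to 9.93 log2), and held 14.9% of the cells of mouse 1A against 4.35 to 4.92% in the others. Cluster 5 (11 cells, 4.38 ± 4.12%, none in mouse 1B) was unnamed, with Gm10800, Gm9892, Hnrnpa0, Cenpq, Ppp4r2, Psme4, Rpl10-ps1, Fkbp3, Eif2s2 and Cpa3 (3.16 to 4.45 log2).

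Inside cluster 3, dividing the cells into 8 clusters separated 31 NK/ILC-like cells (11.8 ± 4.13% per mouse; Il2rb, Klrk1, Ctsw, Ccr8, Klrc1, Cd3g, Klrd1, tagBFP, Gzma and Klrb1b) from 9 basophil- or mast-like cells with Mcpt8, Prss34 and Gata2 and 7 macrophage-like cells with Adgre1, Csf1r and Apoe. The NK/ILC-like cells lay together by well: 23 of the 31 were among the 32 cells in the first 8 wells of the 4 correction sets (6, 8, 2 and 7 of 8), and 8 among the 229 later cells. In 3 sets these were unbroken runs of 6, 8 and 7 wells, the last of which crosses from mouse 1A to 2A by label. Outside the first 8 wells the share was 3.38 ± 2.68% per mouse, so the share in all cells need not be that of ETPs at large. Rora was detected in 58.1% of the NK/ILC-like cells against 20.6% of cluster 1, Bcl11b in 25.8% against 10.3% and Id2 in 93.5% against 79.4%, whereas Gata3 was detected in 80.7% against 88.7%. These shares join plates that differ; in the first pool Rora was detected in 7 of 19 NK/ILC-like cells against 5 of 64 of cluster 1 and Bcl11b in 3 against 2, and in the second pool Rora in 11 of 12 against 15 of 33 and Bcl11b in 5 against 8. Across the other 6 of the 8 clusters, which also differ in their plates, Rora was detected in 14.3 to 36.4% of cells and Bcl11b in 0 to 36.4%. Of the NK/ILC-like cells, 21 of the 23 in the first 8 wells and 4 of the 8 later ones had Gata3. Gata3 was detected in 47.4% of the dendritic-like and 28.6% of the macrophage-like cells. Against the 5 clusters the adjusted Rand index was 0.963 with 4 clusters, 0.809 with 8, 0.713 without centring per plate and 0.436 with Leiden clustering.

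**Figure D3:**
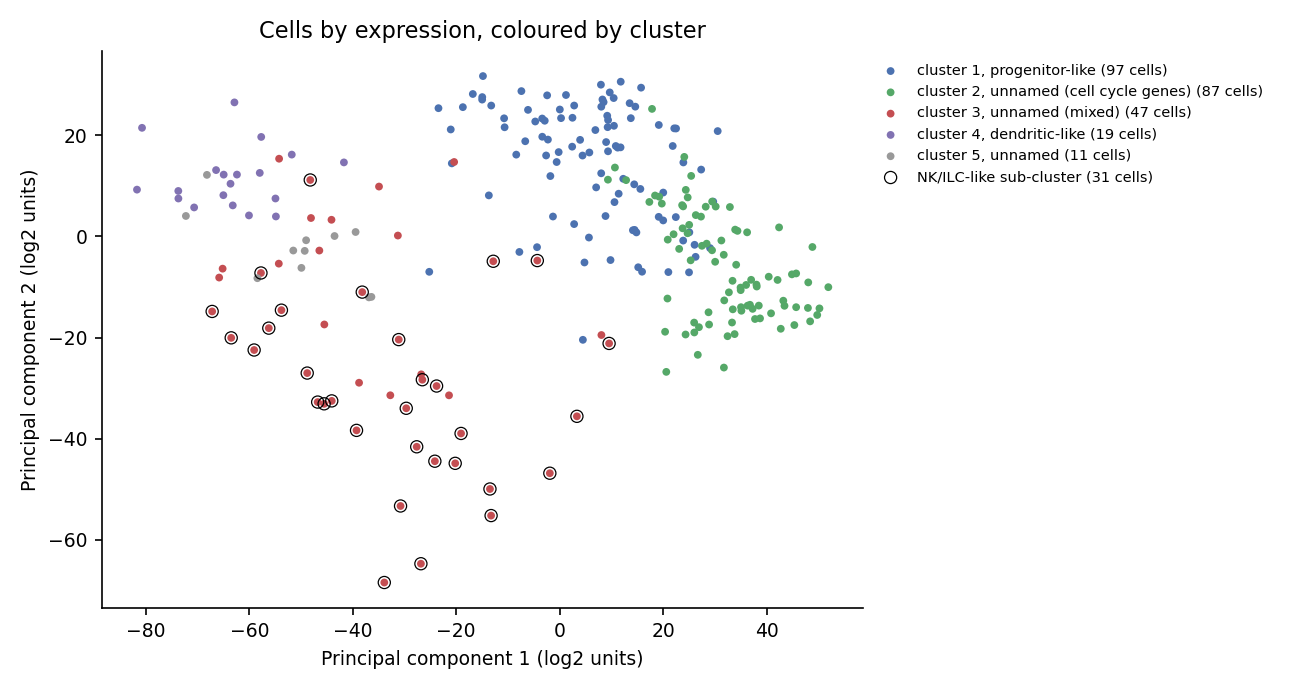
All cells on principal components 1 and 2 (log2 units), coloured by the 5 clusters, with the 31 NK/ILC-like cells ringed. The 19 dendritic-like cells and the 47 cells of cluster 3 lie mostly at lower values of component 1 than the 97 progenitor-like and 87 cycling cells.

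In the planned test, cells with more Rora carried more transcripts of 8 genes, among them receptors of lymphocytes. Besides its own reporter transcript mTeal (adjusted p = 2.29e-10, 0.93 log2 per SD of Rora), Rora rose with Icos, a costimulatory receptor (mean rho 0.340 ± 0.232, adjusted p = 0.0249, 0.62 log2), and Klrb1b, an NK lectin-like receptor (0.314 ± 0.202, adjusted p = 0.0404, 1.13 log2). It also rose with Ikzf3, which encodes Aiolos (0.320 ± 0.251, adjusted p = 0.0404, 0.97 log2), the Notch ligand Dll1 (0.316 ± 0.238, adjusted p = 0.0404, 0.63 log2), the small GTPase gene Rab19 (0.373 ± 0.267, adjusted p = 0.00691, 0.68 log2) and Ehhadh, an enzyme of peroxisomal fatty acid oxidation (0.388 ± 0.105, adjusted p = 0.000627, 0.39 log2). These genes had a positive rho in 4 of 4 mice. Of 12431 genes tested with limma, 8 were positively associated with Rora and 0 negatively, with 845 at unadjusted p < 0.05. Without mouse 1A 19 genes were called, without 1B 4 and without 2B 1. None (0) was called in limma without plate adjustment (310 at unadjusted p < 0.05), without the NK/ILC-like cells and the cells of other types (719), or without the first 8 wells of each correction set (807), while the median absolute rho of the 8 genes was 0.395, 0.378 (5 still tested) and 0.353 (7 still tested) against 0.330. The median absolute rho of the 8 genes was lower in other settings. It was 0.25 without mouse 1B (2 called again), 0.26 with aligned zero levels (5) and 0.275 with the correction set as covariate (3). Most cells with Rora lie below a level of 10. With levels under 10 set to 0, 1 of the 8 genes was called again, and 6 of the 7 still tested kept their sign. With Pearson correlation 2 of the 8 were called again and 7 kept their sign. In mouse 1B, Rora rests on 3 detected cells.

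The ILC list rose with Rora as a group in camera with its preset correlation, and the call was lost with an estimated one. Of its 23 genes, 18 had a positive rho (median 0.119, adjusted p = 1.1e-09, adjusted p = 0.377 with an estimated correlation). Over all genes 2 members passed, Icos and Klrb1b, and 10 passed when adjusted over the list alone, among them Zbtb16, which encodes PLZF (0.298), Lta (0.246), Pdcd1 (0.223), Il18r1 (0.208) and Il7r (0.176). NK genes rose (adjusted p = 0.0016, 0.382 with an estimated correlation; 0 members over all genes, 2 adjusted over the list alone, Klrk1 0.262 and Tbx21 0.214), as did LTi/ILC3 genes (adjusted p = 0.0203; 0 and 2 members, Lta and Nrp1 0.197) and dendritic genes (adjusted p = 0.041; 0 and 0, the largest Xcr1 0.177 and Cd74 0.164, not past the threshold). The progenitor list fell (adjusted p = 0.000912, 5 of 19 genes positive; 0 members, and 1 adjusted over the list alone, Spi1, which encodes PU.1, at -0.236, with Mycn at -0.185 not past either), as did macrophage genes (adjusted p = 0.00463; 0 and 0, C1qb -0.186 and C1qc -0.149) and Notch targets (adjusted p = 0.0367; 0 and 0, Hes1 -0.126 and Nrarp -0.105). With an estimated correlation the adjusted p of these lists was 0.377 to 0.382. The other 11 lists had adjusted p = 0.0663 to 0.966: T specification, gamma-delta T, myeloid, B cell, erythroid and megakaryocyte, mast and basophil, thymic stroma, S phase, G2M phase, immediate early and Y-linked genes. Without the first 8 wells of each correction set, camera kept the ILC (adjusted p = 0.0134) and dendritic calls (0.00231), both 0.521 with an estimated correlation. The progenitor (0.184, 9 of 19 positive), NK (0.28), LTi/ILC3 (0.532), macrophage (0.142) and Notch target calls (0.234) were lost. B cell genes were called up there (0.0469) and G2M genes down (0.00719).

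Bcl11b rose with 12 genes, among them T-cell receptor gamma transcripts, and the median rho of the 12 was lower once the correction sets were allowed for. The joining segments Trgj2 (0.408 ± 0.153, adjusted p = 0.00686, 0.37 log2 per SD) and Trgj1 (0.399 ± 0.18, adjusted p = 0.0141, 0.79 log2) and the constant segments Tcrg-C1 (0.342 ± 0.154, adjusted p = 0.0401, 1.30 log2) and Tcrg-C2 (0.317 ± 0.091, adjusted p = 0.0447, 0.74 log2) were positive in 4 of 4 mice. These segments lie in a single locus on chromosome 13 (Trgj1 at 19210343 to Trgj2 at 19311304 in GRCm38), and similar segments can share reads, so they are not independent genes. Esm1, a secreted proteoglycan, had the highest rho (0.414 ± 0.168, adjusted p = 0.00686, 0.69 log2), and the tyrosine phosphatase genes Ptpn14 (0.394, adjusted p = 0.0279) and Ptpn13 (0.363, adjusted p = 0.0208), Khdc1a (0.361), the tubulin gene Tubb2b (0.359), Zfp719 (0.339) and Fhit (0.336) followed, all positive in 4 of 4 mice. In all 12 of 12431 genes were positively and 0 negatively associated in limma (1034 at unadjusted p < 0.05). The median absolute rho of these 12 genes was 0.362. The count falls to 4 without mouse 1A (median 0.346) and 3 without 2A (0.397). It falls to 0 without mouse 1B (875 at unadjusted p < 0.05, median 0.308), without 2B (972, 0.409 with 9 genes still tested), without plate adjustment (1380, 0.401) and without the first 8 wells of each correction set (854, 0.362). With the correction set as a covariate it was 0 (770) and the median 0.224, with levels under 10 set to 0 it was 0 (824) and 0.227, and with the sets in place of the mice 5 of the 12 genes were called again (0.223). With aligned zero levels, which remove differences between sets in the level at no reads, 6 of the 12 were called again (median 0.245). Bcl11b was detected in 2 cells of mouse 1B and 4 of mouse 1A.

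The gamma-delta T list rose with Bcl11b (camera adjusted p = 0.00158, 6 of 8 genes positive, adjusted p = 0.377 with an estimated correlation), with Tcrg-C1 and Tcrg-C2 past the threshold over all genes and 3 genes when adjusted over the list alone (also Trdc, 0.30). The T specification list rose (adjusted p = 0.0265, 13 of 21 genes; 0 members over all genes, 2 adjusted over the list alone, Tcf7 0.284 and Il2ra 0.213). S phase genes fell (adjusted p = 0.000377, 5 of 42 positive; 0 and 0, Atad2 -0.157 and Fen1 -0.131), as did macrophage (adjusted p = 0.00373; 0 and 1, Csf1r -0.219, with Adgre1 -0.166), myeloid (adjusted p = 0.0203; 0 and 1, Csf1r, with Prtn3 -0.133) and progenitor genes (adjusted p = 0.0317; 0 and 0, Spi1 -0.179 and Cd34 -0.174). With an estimated correlation the adjusted p of these lists was 0.377 to 0.382. The ILC list was not called for Bcl11b (adjusted p = 0.359). It had 0 members past the threshold over all genes and 4 adjusted over the list alone, the largest Icos 0.303 and Tcf7. The other lists had adjusted p up to 0.787. Without the first 8 wells of each correction set, camera lost the S phase (adjusted p = 0.793, 23 of 42 positive) and T specification calls (0.179). The gamma-delta T, macrophage, myeloid and progenitor calls were kept (0.00159 to 0.0375). NK and thymic stroma genes were called up there (0.0329 and 0.00355).

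Gata3 rose with T-cell receptor beta and T-cell signalling genes. Lck (0.346 ± 0.115, adjusted p = 0.000307, 1.32 log2 per SD of Gata3), the T-cell receptor beta segments Trbj1-3 (0.364 ± 0.093, adjusted p = 8.27e-05, 0.75 log2), Trbc1 (0.316 ± 0.094, adjusted p = 0.00324, 1.41 log2) and Trbc2 (0.269 ± 0.108, adjusted p = 0.0274, 1.41 log2) and the cytokine signalling factor Stat3 (0.314 ± 0.121, adjusted p = 0.00324, 0.79 log2) were positive in 4 of 4 mice. Tcf7 (0.258), Tox (0.259) and Cd27 (0.271) also rose, with adjusted p = 0.0362, 0.0362 and 0.0265. Csf2rb2, an IL-3 receptor chain (-0.280 ± 0.107, adjusted p = 0.0177, -1.18 log2), and Il13ra1 (-0.267 ± 0.095, adjusted p = 0.0278, -0.53 log2) fell in 4 of 4 mice. The reporter transcript hCD2 had the highest rho (adjusted p = 1.86e-26, 1.63 log2). In limma 37 genes were positively and 2 negatively associated. The count of 39 falls to 18 without mouse 1A, 8 without 2A, 11 without 2B, and to Stat3 (0.322) and hCD2 (0.642) without the dendritic-, mast- and macrophage-like cells, which held less Gata3. With plate row as a covariate it was 8, and without the first 8 wells of each correction set 86, 31 of the 39 among them. The median absolute rho of the 39 genes was 0.267. Among those still tested it was 0.276, 0.268 and 0.273 without mice 1A, 2A and 2B and 0.265 with plate row. Without the dendritic-, mast- and macrophage-like cells it was 0.201. Trbc1 and Trbc2 lie on chromosome 6 and are near-identical, so their reads can be shared.

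The T specification list rose with Gata3 (camera adjusted p = 5.58e-05, 17 of 21 genes positive, adjusted p = 0.377 with an estimated correlation), with 5 members past the threshold over all genes and 5 adjusted over the list alone: Lck, Trbc1, Cd27, Trbc2 and Tcf7. All 7 Notch targets had a positive rho (adjusted p = 0.00346; 0 members over all genes, 2 adjusted over the list alone, Nrarp 0.224 and Hes1 0.166), against falls with Rora and Id2; the difference between reporter genes was not tested. ILC genes rose (adjusted p = 0.00118; 2 members, Tcf7 and Tox, and 7 adjusted over the list alone), as did NK genes (adjusted p = 0.022, 0.496 with an estimated correlation; 0 and 1, Nkg7 0.202, with Gzmb 0.166). Macrophage (adjusted p = 0.000612; 0 and 0, Adgre1 -0.18 and Cd68 -0.139), dendritic (adjusted p = 0.00386; 0 and 0, Flt3 -0.177 and Zbtb46 -0.158), myeloid (adjusted p = 0.00506; 0 and 1, Cebpa -0.241, with Irf8 -0.122) and mast and basophil genes (adjusted p = 0.0317; 0 and 0, Mcpt8 -0.119 and Prss34 -0.107) fell. With an estimated correlation the adjusted p of these lists was 0.377 to 0.496, and the other 10 lists had adjusted p = 0.0874 to 0.836. Without the first 8 wells of each correction set, camera lost the ILC (adjusted p = 0.245), NK (0.885), myeloid (0.102) and mast and basophil calls (0.082). The T specification, Notch target, macrophage and dendritic calls were kept (0.000132 to 0.00835). That setting keeps most of the dendritic-, mast- and macrophage-like cells, of which 47.4, 44.4 and 28.6% had Gata3. The list results for Gata3 are thus not separated from the mixture of cell types. Without these cells 17 of the 72 list tests of all reporter genes were called, against 27 with them. Progenitor genes were called up there (0.0119).

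Over all cells Id2 rose with NK receptors and fell with progenitor regulators, and these calls were lost when the first 8 wells of each correction set were left out. Klrd1, which encodes CD94, had the highest rho after the reporter transcript tagBFP (0.454 ± 0.171, adjusted p = 1.69e-07, 1.55 log2 per SD of Id2), followed by the integrin chain Itgb2 (0.399 ± 0.096, adjusted p = 3.74e-05, 1.5 log2), Cd226, which encodes DNAM-1 (0.395 ± 0.148, adjusted p = 4.04e-05, 0.99 log2), and the lysosomal enzyme gene Arsb (0.383 ± 0.097, adjusted p = 0.000101, 1.61 log2). Sox4 (-0.322 ± 0.108, adjusted p = 0.00358, -1.36 log2) and the progenitor factor Myb (-0.308 ± 0.172, adjusted p = 0.00662, -1.31 log2) fell, as did Atpif1 (-0.291), Tbc1d14 (-0.290) and Gpc6 (-0.283), with adjusted p = 0.0161, 0.0165 and 0.023; each had its sign in 4 of 4 mice. For tagBFP adjusted p was 5.3e-41 (2.92 log2). In limma 46 genes were positively and 10 negatively associated, 48 of them with the same sign in all 4 mice. The count of 56 falls to 3 without mouse 1B, 10 without 2A, 17 with the correction set as a covariate, 3 with plate as unit and 4 with plate row as a covariate, where the median absolute rho of the 56 genes was 0.226 against 0.307. It falls to tagBFP alone (0.714) when the 31 NK/ILC-like cells, whose leading genes include Klrd1, Klrk1 and tagBFP, and the cells of other types are left out. The 32 cells in the first 8 wells of each correction set were chosen by position. But 8 was the longest run of NK/ILC-like cells, and 23 of the 32 are such cells. The loss of calls without them was thus also partly fixed by the choice. Leaving these 32 cells out also left tagBFP alone (0.702). The median of the 49 genes still tested was then 0.165 (Klrd1 0.269, Sox4 -0.141, Myb -0.145).

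All 8 NK genes tested had a positive rho with Id2 (median rho 0.265, camera adjusted p = 3.1e-16, adjusted p = 0.377 with an estimated correlation). Over all genes 4 passed, Klrd1, Klrk1 (0.356, 4 of 4 mice), Ncr1 (0.313, 4 of 4) and Tbx21 (0.277, 3 of 4), and 7 adjusted over the list alone. ILC genes rose (adjusted p = 1.1e-05; 3 members, Klrb1b 0.315, Cd7 0.306 and Il2rb 0.304, the last in 3 of 4 mice, and 9 adjusted over the list alone), as did G2M genes (adjusted p = 2.84e-05, 45 of 52 positive, 0.436 with an estimated correlation) and LTi/ILC3 genes (adjusted p = 0.028; 0 and 2, Lta 0.218 and Ltb 0.178). The progenitor list fell (adjusted p = 0.000441, 3 of 19 positive), with Sox4 past the threshold over all genes and 6 adjusted over the list alone (also Kit -0.220, Erg -0.216, Mycn -0.205, Nfe2 -0.194 and Lyl1 -0.192), and so did Notch targets (adjusted p = 0.00637; 0 and 0, Myc -0.159 and Hes1 -0.143). With an estimated correlation the adjusted p of these lists was 0.377 to 0.436. The other 12 lists had adjusted p = 0.0505 to 0.968. Without the first 8 wells of each correction set, camera kept the NK call for Id2 (median rho 0.0755, adjusted p = 0.0268, 0.577 with an estimated correlation). The other called lists lost their calls: ILC (adjusted p = 0.861), G2M (0.861, 26 of 52 positive), LTi/ILC3 (0.25), Notch targets (0.278) and progenitor (0.885, 10 of 19 positive). Macrophage and dendritic genes were called up there (adjusted p = 0.00244 and 0.000742).

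**Figure D4:**
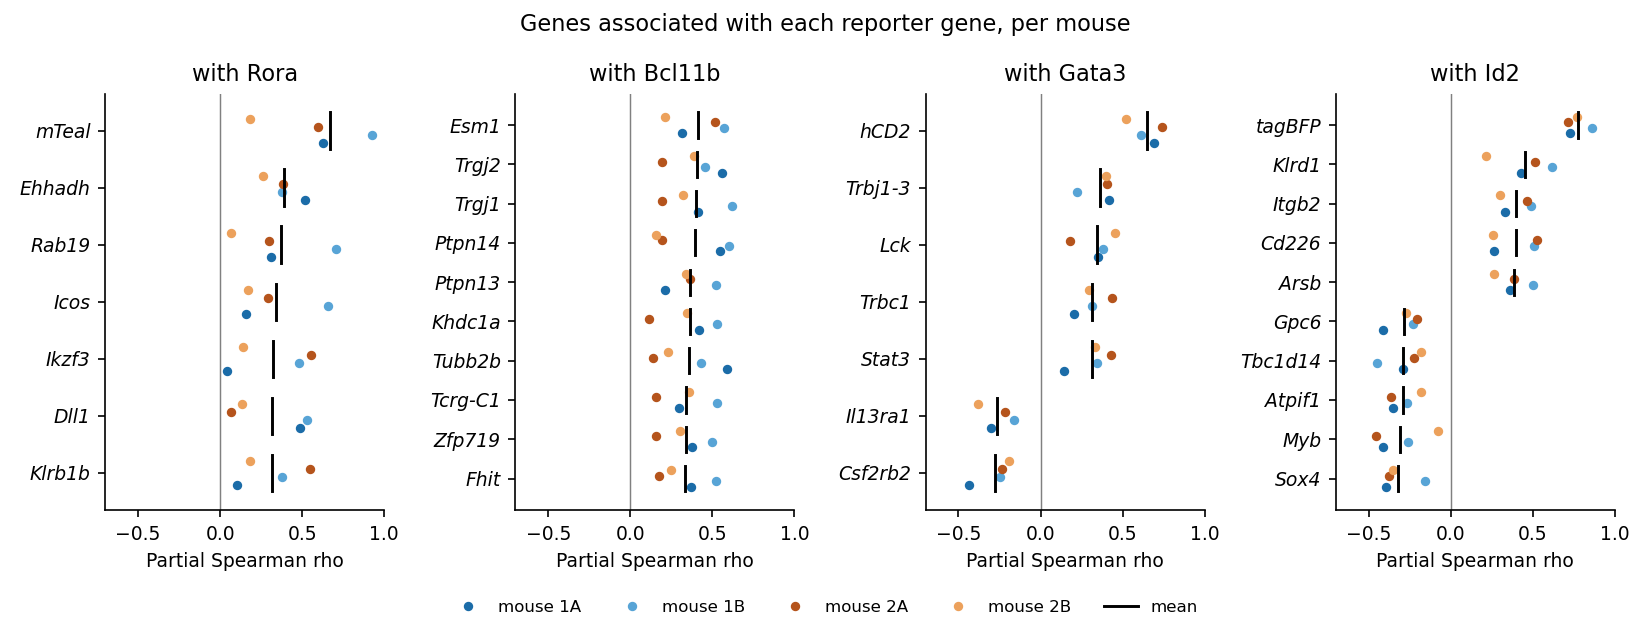
Partial Spearman rho of each named gene with Rora, Bcl11b, Gata3 or Id2 in each of 4 mice (points) with the mean (bar). The reporter transcripts tagBFP (0.777), mTeal (0.669) and hCD2 (0.648) lie above the other named genes, whose means lie between -0.322 and 0.454.

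Across the 72 list tests 27 were called with camera, 14 up and 13 down, and 14 without mouse 2A. With an estimated correlation 0 were called and with fry 0 (smallest adjusted fry p 0.171), so the list results rest on the preset correlation. In 6 tests, none of them called, the median, mean and test differed in sign.

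The reporter genes themselves showed no association that passed the test inside mice. The mean rho was 0.110 ± 0.101 for Rora with Bcl11b, -0.031 ± 0.145 for Rora with Gata3, 0.129 ± 0.076 for Rora with Id2, 0.132 ± 0.158 for Bcl11b with Gata3, -0.117 ± 0.052 for Bcl11b with Id2 and 0.048 ± 0.197 for Gata3 with Id2. Rora with Id2 was positive and Bcl11b with Id2 negative in 4 of 4 mice (adjusted p = 0.765 and 0.649 in limma). For the difference between Rora and Bcl11b, 0 of 12430 genes passed in limma, with 877 at unadjusted p < 0.05. The reporter transcript mTeal came nearest, with a z difference of 0.604 ± 0.573, higher with Rora in 4 of 4 mice (adjusted p = 0.0552).

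The T specification and ILC scores had a positive rho among the cells of each labelled mouse, which the test could not call. Their mean rho was 0.372 ± 0.137, and that of T specification and myeloid scores -0.123 ± 0.083. These 2 of 15 relations had the same sign in 4 of 4 mice, with an exact sign-flip p of 0.13 each (two-sided, rounded), the smallest that 4 mice allow, so no relation could pass 0.05. Without the cells of other types the T specification and ILC scores gave 0.390 ± 0.093, and 0.290 ± 0.117 without the NK/ILC-like cells as well. The relation of T specification and myeloid scores was lost without the cells of other types (0.0001 ± 0.122, no common sign). Progenitor and ILC scores gave -0.181 ± 0.282 and progenitor and T specification scores -0.069 ± 0.190, the latter -0.213 ± 0.110 with the same sign in 4 of 4 mice without the cells of other types. Without mouse 2A or without 2B, 5 relations had a common sign.

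Of the 4 Y-linked transcripts, Ddx3y and Eif2s3y split the labelled mice, and Uty and Kdm5d did not. Ddx3y was detected in 5 of 67 cells of mouse 1A and 5 of 69 of 1B, against 43 of 64 of 2A and 49 of 61 of 2B, and Eif2s3y in 10, 1, 45 and 47 cells. Uty was detected in 30, 42, 43 and 45 cells and Kdm5d in 46, 53, 53 and 51 cells of mice 1A, 1B, 2A and 2B. By the 4 correction sets Ddx3y was detected in 4 of 65, 61 of 73, 3 of 67 and 34 of 56 cells. Any of the 4 Y-linked genes was detected in 83.6, 85.5, 96.9 and 98.4% of cells of mice 1A, 1B, 2A and 2B, and Xist was not analysed here. Labelled mice and correction sets do not hold the same cells, and the labelled mice were kept as the units of every test.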

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

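The tests on mTeal, Rora levels and the animal for plate JW8, on place on the plate, and both tests of the mouse labels were chosen after their results had been seen; the others were written before. Among 64 groups of 4 mice, 2 held a mouse far from the others by Dixon's ratio of the gap to the range, and chance flags about 1 in 20 groups. The share of cells in the dendritic-like cluster 4 stood apart in mouse 1A (14.9% against 4.35 to 4.92%, ratio 0.946). The rho of Trbj1-3 with Gata3 was lower in mouse 1B (0.223 against 0.398 to 0.420, ratio 0.888).

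Rora was detected in 21 of 25 cells of plate JW8 (84%, 63.9 to 95.5%) against 50 of 236 elsewhere (21.2%). Depth is argued against, since among the 43 cells of other plates with at least the median number of detected genes of JW8, 20.9% (10 to 36%) had Rora, and so is better detection of all rare transcripts, since Rora lies at percentile 99.8 of 2380 genes whose median share was 24% on JW8 and 19.5% elsewhere. Placement of Rora-expressing cells on JW8 stays open: mTeal was detected in 52% of its cells against 8.47% (5.25 to 12.8%), yet at a level of at least 10 in 4% against 4.66%, which is why the test was left undecided after its values were seen. Reads from other libraries of the pool stay open too: at a level of at least 10 Rora was found in 12% of JW8 cells, above the bound of 11.3% set for exclusion, but this rests on 3 cells whose interval (2.55 to 31.2%) holds the 7.20% elsewhere, so the bound was judged too strict after the outcome. JW8 holds cells of mouse 2B alone, but the animal is argued against as the whole cause, since Rora was detected in 30.6% of the cells of mouse 2B on plate JW7 (11 of 36, 16.3 to 48.1%) and in 19.4% of the cells of the correction set of JW8 on plate AF2 (6 of 31, 7.45 to 37.5%, first pool).

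Genes of the dendritic-like cells were detected in many other cells: the 50 leading genes were found in a median of 42.4% of the 242 other cells (14.9 to 99.2%). Index switching between wells that share an index may contribute, since the 154 cells that share an index with a dendritic-like well of their pool had levels 0.32 log2 higher than the 88 that share none (permutation p = 0.0053). The share of other cells with a gene followed its level in the dendritic-like cells (Spearman rho 0.844 across genes, which are not independent). A single outside source would give this, but low-level expression in the other cells could as well, so this value does not decide. Place on the plate stays open. For wells of the other pool, not sequenced together, the difference was -0.25 log2, opposite in sign to what place would give but without a permutation test. Index switching cannot act between pools, so a difference of this size can arise without it. This also weakens the 0.32 log2 within the pool. No biological explanation was tested, and low-level expression of these genes in ETPs remains possible beside reads from other libraries.

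The labelled mice and the 4 correction sets split the cells differently. A candidate explanation is that mouse ids were entered in another order of the plates: along plates JW7, AF1, AF2 and JW8 in well order the sets form 4 blocks, and all 4 can have the size of a labelled mouse (80, 73 to 76, 73 to 76 and 71 cells). Whether the correction sets follow the animal stays open: set and labelled mouse predict opposite shares of the Y-linked Ddx3y and Eif2s3y for only 10 cells, of which 5 of 7 in sets high in these genes and 0 of 3 in sets low had either (exact p = 0.167). The labels were not changed, and no biological explanation was tested.

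Chance pairing of cells within a plate and mouse is argued against as the source of the counts of associated genes. With each reporter gene reassigned among the cells of a plate and mouse, 1 of 100 draws, the real one, called as many genes for Rora (8, highest other 2), Bcl11b (12, highest other 3), Gata3 (39, highest other 1) and Id2 (56, highest other 1). This excludes neither wrong mouse labels nor differences between cell types or between correction sets as the ground of an association. The reassignment also mixed cells of different sets, whose levels at no reads differ. With the set as covariate, 3 of the 8 Rora and 0 of the 12 Bcl11b genes were called again. For Gata3 25 of the 39 and for Id2 17 of the 56 were called again.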

How the results depend on the processing

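The alternatives with correction sets, aligned zero levels, levels under 10 set to 0, plate row, 5 detected cells, plate JW8, NK/ILC-like cells and the first 8 wells of each correction set were chosen after the data were seen. The counts of associated genes moved with most settings, and for each the cause was not tested unless fewer genes, cells or mice entered by construction. Of 1175 values for 45 named called associations, 683 kept direction and side of the threshold, 491 kept direction and lost the call, and 1 reversed (Zfp719 with Bcl11b, -0.0486 with levels under 10 set to 0). The relations of tagBFP with Id2 and of hCD2 with Gata3 passed under every alternative run. At least 2000 detected genes changed nothing, since every cell passes it.

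For Rora (8 genes) the counts were 27 with Pearson correlation, 3 with S and G2M scores, 3 with the correction set as covariate, 53 with it as unit, 1 without and 2 with swapped doubtful wells, 3 with genes in 25% of cells, 3 with levels under 10 set to 0, 38 with median-ratio rescaling, 38 with aligned zero levels, 4 with mice of at least 5 detected cells, 13 without depth adjustment, 2 without the low-gene filter, 2 without plate JW8 and 1 with plate row. They were 0 with pseudocount 10 (1201 at unadjusted p < 0.05 in limma), the first pool only (597), no plate adjustment (310), plate as unit (580), without NK/ILC-like and other cell types (719) and without the first 8 wells of each set (807); leaving out 1 mouse gave 1 to 19. For Bcl11b (12) they were 1 with Pearson correlation, 6 without or with swapped doubtful wells, 5 with genes in 25% of cells, 4 without the low-gene filter and 6 with plate row. They were 0 with pseudocount 10 (795 at unadjusted p < 0.05 in limma), the set as covariate (770), the first pool (1233), levels under 10 set to 0 (824), mice of at least 5 detected cells (795), no plate adjustment (1380), plate as unit (569), without NK/ILC-like and other cell types (796) and without the first 8 wells of each set (854); leaving out 1 mouse gave 0 to 4. For Gata3 (39) they were 102 with Pearson correlation, 77 with pseudocount 10, 14 with S and G2M scores, 8 with the first pool, 18 with levels under 10 set to 0, 10 with median-ratio rescaling, 111 without depth adjustment, 2 without other cell types, 2 also without NK/ILC-like cells, 15 without plate JW8, 1 with plate as unit, 8 with plate row, 86 without the first 8 wells of each set and 68 with aligned zero levels; leaving out 1 mouse gave 8 to 41. For Id2 (56) they were 216 with Pearson correlation, 208 with pseudocount 10, 17 with the set as covariate, 144 with it as unit, 30 with the first pool, 101 with levels under 10 set to 0, 177 with median-ratio rescaling, 161 without depth adjustment, 34 without other cell types, 1 also without NK/ILC-like cells, 3 with plate as unit, 4 with plate row, 1 without the first 8 wells of each set and 116 with aligned zero levels; leaving out 1 mouse gave 3 to 69. Rescaling moved the split of higher to lower calls to 34 and 4 for Rora and 14 and 4 for Bcl11b with median ratios, and to 31 and 7 and 13 and 4 with aligned zero levels. Settings that call more genes were not adopted.

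For the difference between Rora and Bcl11b (0 in limma, 877 at unadjusted p < 0.05) 14 genes passed with Pearson correlation, 5 with the set as unit, 2 in the first pool, and 1 each with S and G2M scores, doubtful wells left out or swapped, median-ratio rescaling, no depth adjustment, other cell types left out, plate row and aligned zero levels; leaving out 1 mouse gave 0 to 1. Of the 72 list tests (27 called) 0 were called with an estimated correlation and 0 with fry, 17 without other cell types and 7 also without NK/ILC-like cells, 18 without the first 8 wells of each set, and 14 to 31 with 1 mouse left out. Of the score relations 2 had a common sign in all mice, 6 without depth adjustment, 5 with the set as unit, and 2 to 5 with 1 mouse left out. At a level of at least 10 the share of cells fell to 7.77% for Rora, 71.5% for Gata3 and 66.4% for Id2, and the share with any Y-linked gene from 91.1 to 62.6%. The dendritic-like share was 7.22% with 4, 5 and 8 clusters and without centring and 9.56% with Leiden clustering. No paired analysis was possible because the labels name 1 group. Few cells with reads limit the rare genes: with Rora and Bcl11b detected in 3 and 2 cells of mouse 1B, an absent association there was not detectable.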

Other observations

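The tests without NK/ILC-like cells, without the first 8 wells of each correction set and with correction sets as units, and the rule that names cells of other types, were chosen after the results had been seen. Without the cells of other types, 34 genes were called with Id2 (median absolute rho of the 56 genes called before 0.329) and 2 with Gata3 (0.201). Without the NK/ILC-like cells as well, tagBFP (0.714) was the 1 gene called with Id2, and the median of the genes called before and still tested was 0.127 for Id2 and 0.182 for Gata3. The NK/ILC-like cells were recognised by leading genes that include genes called with Id2 (Klrd1, Klrk1, Klrb1b, Il2rb and tagBFP), so the loss of those calls was partly fixed by the choice of cells and does not show how the association arises. For Rora and Bcl11b, with 0 genes called in limma (719 and 796 at unadjusted p < 0.05), the median was 0.378 and 0.356.

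Of the 31 NK/ILC-like cells, 23 lay among the 32 cells in the first 8 wells of the 4 correction sets. Leaving those 32 cells out called tagBFP alone with Id2 (0.702) and 86 genes with Gata3. The median of the genes called before and still tested was 0.165 for Id2 and 0.287 for Gata3. The cells were chosen by position, but the number 8 came from the longest run of NK/ILC-like cells. The loss of Id2 calls was thus partly fixed by the choice here too. For Rora and Bcl11b, with 0 genes called in limma (807 and 854 at unadjusted p < 0.05), the median was 0.353 and 0.362. Apart from tagBFP, the Id2 calls were not made without these cells, which lie together by well. Whether those wells were filled in another way than the rest is not given in the sources used here.

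Taking the authors' correction sets in place of the labelled mice called 53 genes with Rora, 16 with Bcl11b, 50 with Gata3 and 144 with Id2, against 8, 12, 39 and 56. Of the genes called by labelled mouse, all 56 with Id2, 34 with Gata3, 5 of the 8 with Rora and 5 of the 12 with Bcl11b were called again. The median absolute rho of the 12 Bcl11b genes was then 0.223.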
